A study of Zea mays with 36 samples.

How the data were processed

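Root RNA of nitrate-treated and control seedlings was measured on spotted cDNA arrays with 2 dyes. Per the labels, 12 replications of separate plants were used, 6 treated for 30 min and 6 for 24 h, and each consisted of a nitrate sample and a control sample. The labels name the dye of each channel, and from them every ratio was turned to nitrate over control. At 30 min nitrate was on Cy3 in replicates 1, 3 and 5 and on Cy5 in replicates 2, 4 and 6, and at 24 h the reverse. Each array was scanned at a High, a Medium and a Low power setting, so that the 36 scans are 12 replicates of 3 scans each.

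The deposited scan files give, per the file headers, the mean and median foreground intensity and the mean and median local background intensity of each spot in both channels, on the scanner's linear scale up to 65535. The scanner, the image analysis software and the authors' normalization are not given in the sources used here. The same files hold normalized values of each channel and a final value. The authors' normalized values behaved as the natural log of the background-subtracted signal, with slopes against it of 0.96 to 1.03 for Cy5 and 0.91 to 1.04 for Cy3, and the deposited final value was equal to Cy5 minus Cy3 on that natural log scale in every scan (largest gap 8.9e-16). The series value table held the same numbers (largest gap 5e-10). Its scale and direction were thereby settled, and medians of the final values between -0.0324 and 0.0595 show that the scans were centred near 0. The method of that centring stays unknown. The number of columns from samples outside the labels was 0.

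The scanner intensities were used for the main results. They were read in R 4.3.3 and processed with limma 3.58.1. Foreground means were corrected for the median local background by the normexp method with an offset of 50, and log ratios were normalized by loess within each scan. Ratios were turned to nitrate over control, the 3 scans of a replicate were averaged, and spots of one probe were averaged. This reduced 7888 spots to 7688 probes, of which 200 had more than 1 spot. The mean log2 ratios of a pair of spots of one probe correlated at 0.75 at 30 min and 0.79 at 24 h. Spot numbers ran up to 12160, and numbers missing from the files were not analysed here. Saturated spots were kept. Of the probes named by rank, 0 were at background in all replicates of a group or saturated in a Low scan. Loess assumes that most probes do not change, so that a shift common to all transcripts would be removed.

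A linear model was fitted to the 12 replicate values of each probe with 3 coefficients, the ratio at 30 min, the ratio at 24 h and a Cy5 over Cy3 dye effect common to all arrays. It left 9 residual degrees of freedom, to which limma's empirical Bayes step added 10.9. Both times thus shared one estimate of the spread. Probes with a Benjamini-Hochberg adjusted p under 0.05 over all 7688 probes were counted, separately at 30 min, at 24 h and for the ratio at 24 h minus the ratio at 30 min. The dye effect itself passed for 3353 probes (43.6%), with a median size of 0.35 where Cy5 was higher and -0.29 where Cy3 was higher. With 3 replicates of each orientation at both times, a dye effect common to the arrays of a time cancels in the mean ratio. A dye effect that differs between arrays does not cancel, and at 30 min the Cy5 over Cy3 patterns of the replicates correlated with the mean 24 h pattern at -0.14 to 0.75. The fitted log2 ratios had a median standard error of 0.12. Values per probe are means and SDs of the 6 replicates of a time, and the SE of a difference comes from the model.

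The steps from scan to call were tested on simulated scans of 7688 probes built from the real spot brightness, background and residual spread, in which 200 probes were changed at each time. At 30 min the calls recovered 53.7% of changes of 0.5 on the log2 scale, 98.5% of changes of 1 and 100% of changes of 2, and 4.0% of the calls were false. At 24 h the shares were 52.2%, 97.0% and 100%, and 6.21% of the calls were false. The simulated arrays all had the same dye effect, and their noise was independent between probes. The shares recovered and the shares of false calls therefore do not cover dye effects that differ between arrays, as those at 30 min did. Noise was also drawn from the same spread at both times. With each time fitted alone, the median residual SD was 0.264 at 30 min and 0.217 at 24 h. The simulated recovery at 30 min may thus be too favourable.

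The rule for naming probes was fixed before the data were examined. It asked for probes with a gene symbol or description and, where there were none, for at most 2 IDs that rose and 2 that fell. It was applied to each comparison, over probes that passed and, at a single time, had one sign in all 6 replicates, ranked by the size of the log2 ratio. The reference table of the Zm-B73-REFERENCE-NAM-5.0 assembly named 1 probe through a synonym, 0 probes matched its RefSeq accessions, and 2 probes carried a name of their own in the files. These 3 probes are reported too. The 22 gene lists fixed beforehand, among them markers of shoot and kernel, matched 0 probes, so neither tests of gene lists nor a check for other plant parts could be made. Slide and scan dates are not given in the sources used here, so batches could be looked for only in the signals.

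Alternatives covered the background correction, the normalization, each scan power alone, the choice of scan for each spot, dim probes, the dye effect, separate fits, the variance model, array weights, the deposited values, a stricter threshold, the replicate number and each replicate left out. Settings without the most saturated scans and with other treatments of the dye effect and of 30 min replicates 5 and 6 were added after the data had been seen. The figures were drawn with matplotlib 3.10.9.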

Results

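Transcript levels were compared between roots of maize seedlings given nitrate and roots kept without it. Maize (Zea mays, inbred line B73, the line behind the maize reference genome) was grown on germination paper in 5 mM calcium sulfate. Roots were then placed in 5 mM calcium nitrate or in fresh 5 mM calcium sulfate. The nitrate roots were thus also taken out of calcium sulfate, and effects of the nitrate and of the lost sulfate cannot be told apart here. The exposure lasted 30 min (plants treated on day 11) or 24 h (plants treated from day 10), with 6 biological replicates at each time. Each replicate was a nitrate sample and its calcium sulfate control, labelled with different dyes (Cy3 and Cy5) and hybridised together on 1 spotted cDNA array, a glass slide that carries amplified clones. The dyes were swapped between replicates, with 3 replicates of each orientation at each time. Every array was scanned at 3 power settings, which gave 36 scans of 12 replicates. The arrays measured 7888 spots, which made up 7688 probes. Probes are given by the accession of their clone, since all but 3 of them carried no gene name in the files or in the reference table used here. All ratios are nitrate over control, so that a positive log2 ratio means a higher level in nitrate, and the number of arrays limits their precision.

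The scan powers differed as their names say. Median foreground signals ran from 3522 to 32040 units in the High scans, from 1499 to 22110 in the Medium scans and from 477.8 to 1318 in the Low scans. The median share of spots with a saturated channel was 4.45% in the High scans, 0.90% in the Medium scans and 0.0886% in the Low scans. Spots at or below their local background went the other way, with medians of 1.83%, 2.74% and 8.62%. Log2 ratios of the 3 scans of a replicate correlated across probes at 0.72 to 0.93, with a median of 0.83. The 3 scans of a replicate were averaged and counted as 1 value. At 24 h, replicate 3 stood apart with 30.4% saturated spots in its High scan and 21.9% in its Medium scan. Without these scans 89 probes passed at 30 min and 1243 at 24 h, against 88 and 1127 with them.

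**Figure D1:**
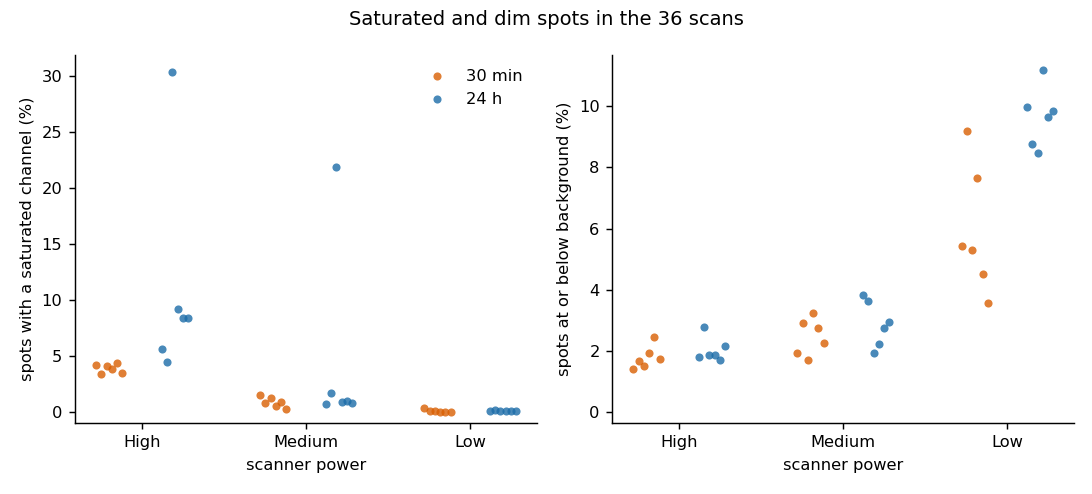
Share of spots with a saturated channel (left, percent) and at or below local background (right, percent) in each of the 36 scans, by scanner power, with 1 point per replicate and colours for the time points. Replicate 3 at 24 h reached 30.4% saturated spots in the High scan and 21.9% in the Medium scan.

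After 30 min in nitrate, 88 of the 7688 probes (1.14%) passed, with 82 higher and 6 lower in nitrate relative to the centre of each scan. The comparison asked which root transcripts respond within minutes of the first contact with nitrate, the main nitrogen source of crops in aerated soil. The median log2 ratio was 0.72 among the higher and -0.55 among the lower probes. A change of more than 2-fold was reached by 25 of the higher probes and by 0 of the lower ones, and 6 rose more than 4-fold.

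The strongest rises at 30 min belonged to BM333948 and DQ011869. BM333948 rose 10.99-fold, a log2 ratio of 3.46 ± 0.60 (SD, n = 6), with values from 2.78 to 4.47 (limma, adjusted p = 4.71e-07). DQ011869 rose 8.23-fold, a log2 ratio of 3.04 ± 0.48 (SD, n = 6), with values from 2.45 to 3.69 (limma, adjusted p = 2.13e-11). Both were higher in nitrate in 6 of 6 replicates, which the naming rule required, and so in both dye orientations. The means were 3.25 (nitrate on Cy5) and 3.67 (nitrate on Cy3) for BM333948, and 3.34 and 2.74 for DQ011869. The falls were shallow. BM073675 fell to 0.67 of the control, a log2 ratio of -0.58 ± 0.34 (SD, n = 6; limma, adjusted p = 0.0421), and BG842333 also to 0.67, a log2 ratio of -0.57 ± 0.25 (SD, n = 6; limma, adjusted p = 0.0463). Each was lower in 6 of 6 replicates, again as the naming rule required. The call of BM073675 was lost under 17 of 32 alternative settings and that of BG842333 under 21 of 32.

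All 6 replicates had the sign of the fitted ratio for 82 of the 88 probes that passed at 30 min. Passing was judged on the same values and by itself favours such agreement. Over all 7688 probes the share was 2.84%, where random signs without dye effects would give 3.12%. The number of passing probes was 55 from the High scans alone, 50 without a dye effect in the model and 58 without 30 min replicate 5, with 0 lower probes in each of these settings. Local background was higher in 30 min replicates 5 and 6, with High-scan Cy3 medians of 1607 and 1700 units against 202 to 757 in replicates 1 to 4. From replicates 1 to 4 alone 39 probes passed (39 higher, 0 lower), from replicates 5 and 6 alone 46 (44 higher, 2 lower), and with a separate dye effect for each set 128 (115 higher, 13 lower). Among the 32 ways to assign nitrate and control to the channels of the 6 arrays, 1 other than the real one gave more probes than the real 88, namely 178, so this count alone does not exclude chance. With the separate dye effects 30 of the 32 could be fitted, the one with 178 not among them, and the highest count other than the real 128 was 8.

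After 24 h in nitrate, 1127 of the 7688 probes (14.7%) passed, about equally split between 562 higher and 565 lower. The comparison asked what distinguishes roots supplied with calcium nitrate for a day from roots kept in calcium sulfate. Rises were larger than falls at the top end. A change of more than 2-fold was seen in 81 higher and 27 lower probes, and a change of more than 4-fold in 15 higher and 0 lower probes. The medians were alike in size, 0.50 for the higher and -0.49 for the lower probes.

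BM333948 had the largest log2 ratio at 24 h as well. It rose 47.3-fold, a log2 ratio of 5.56 ± 1.76 (SD, n = 6; limma, adjusted p = 1.04e-10), and was higher in nitrate in 6 of 6 replicates. Its replicates ranged from 3.03 to 7.93, with a mean of 4.33 where nitrate was on Cy5 and 6.80 where it was on Cy3, and the fitted log2 ratio was 6.20 where each spot was taken from its highest-power scan without saturation, so that the size of the rise was less certain than its direction. BG874013 rose 18.8-fold, a log2 ratio of 4.23 ± 0.99 (SD, n = 6; limma, adjusted p = 4.26e-12), in 6 of 6 replicates. The deepest falls were those of BM076073 and BM080220. BM076073 fell to 0.28 of the control, a log2 ratio of -1.86 ± 0.46 (SD, n = 6; limma, adjusted p = 1.79e-09), and BM080220 to 0.37, a log2 ratio of -1.42 ± 0.56 (SD, n = 6; limma, adjusted p = 1.38e-07). Both were lower in 6 of 6 replicates. For BM333948, BG874013, BM076073 and BM080220 the naming rule required the same sign in all 6 replicates at 24 h. Both probes that led the falls at 30 min also passed at 24 h. BG842333 had a log2 ratio of -0.91 ± 0.48 (SD, n = 6; limma, adjusted p = 0.000106), and BM073675 of -0.81 ± 0.78 (SD, n = 6; limma, adjusted p = 0.000352). BM073675 was lower in only 4 of 6 replicates at 24 h, with a mean of -1.48 where nitrate was on Cy5 and -0.14 where it was on Cy3.

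All 6 replicates had the fitted sign for 553 of the 1127 probes that passed at 24 h and for 9.34% of all probes. Here too passing by itself favours such agreement. The number of passing probes was 514 without a dye effect in the model, 1899 with array weights and 568 at an adjusted p under 0.01. It was 1720 where only replicates 5 and 6 entered for 30 min, and 2043 with separate dye effects for 24 h and for both sets of 30 min replicates.

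**Figure D2:**
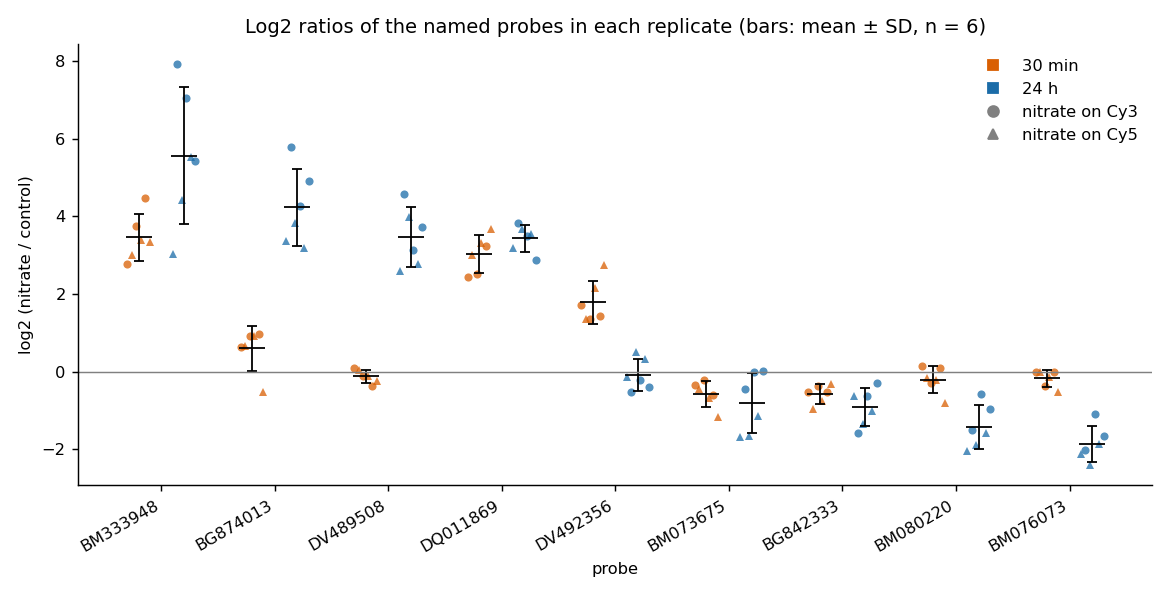
Log2 ratio of nitrate over control (vertical axis) in every replicate for the 9 probes named by rank, with 30 min and 24 h in different colours, circles for nitrate on Cy3, triangles for nitrate on Cy5, and bars for the mean ± SD of 6 replicates. BM333948 and DQ011869 lie above 2.4 in all replicates of both times, while DV489508 lies between -0.38 and 0.09 at 30 min and between 2.60 and 4.58 at 24 h.

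The difference between the responses at the 2 times was tested directly, and 326 probes passed. The ratio was higher at 24 h for 177 of them and lower for 149. Most of these were probes that had moved by 24 h. Among the 177, 176 were higher in nitrate at 24 h, with a median log2 ratio of -0.0083 at 30 min and 0.88 at 24 h. Among the 149, 124 were lower in nitrate at 24 h (medians of 0.040 and -0.77). A further 24 did not pass at 24 h, and 1 was still higher in nitrate.

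Late risers are illustrated by BG874013 and DV489508. BG874013 went from a log2 ratio of 0.60 ± 0.57 (SD, n = 6; limma, adjusted p = 0.285) at 30 min to 4.23 at 24 h, a difference of 3.63 ± 0.27 (SE; limma, adjusted p = 7.84e-08). DV489508 had a log2 ratio of -0.12 ± 0.17 (SD, n = 6; limma, adjusted p = 1) at 30 min and 3.47 ± 0.76 (SD, n = 6; limma, adjusted p = 1.71e-11) at 24 h, a difference of 3.59 ± 0.25 (SE; limma, adjusted p = 3.59e-08). DV492356 showed the opposite course. It rose 3.47-fold at 30 min, a log2 ratio of 1.80 ± 0.55 (SD, n = 6; limma, adjusted p = 3.58e-08), and stood at -0.07 ± 0.41 (SD, n = 6; limma, adjusted p = 0.773) at 24 h, a difference of -1.87 ± 0.19 (SE; limma, adjusted p = 3.61e-06). BM076073 had a log2 ratio of -0.17 at 30 min and differed by -1.69 ± 0.18 (SE; limma, adjusted p = 4.48e-06) between the times. BM333948 rose further, by 2.11 ± 0.45 (SE; limma, adjusted p = 0.00702), a call that was lost under 4 of 32 alternative settings. For DQ011869 the difference of 0.40 ± 0.20 (SE; limma, adjusted p = 0.347) did not pass, and its ratio was above 0 in 12 of 12 replicates. The naming rule required this sign at 30 min but not at 24 h.

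The number of probes passing in the difference was 182 from the High scans alone, 137 without a dye effect, 642 with array weights and 173 at an adjusted p under 0.01. With 30 min replicates 1 to 4 only it was 197, with replicates 5 and 6 only 130, and with separate dye effects for 24 h and for both sets of 30 min replicates 748.

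The 82 probes that were higher in nitrate at 30 min divided by what followed. For 27 of them the ratio was lower at 24 h by the test of the difference, with a median log2 ratio of 0.82 at 30 min and -0.074 at 24 h. DV492356 belonged to these. For 10 the ratio was higher at 24 h, with medians of 0.64 and 1.94, and BM333948 belonged to these. The other 45 did not pass in the difference, and 31 of them were higher in nitrate at both times, with medians of 0.79 and 0.78. The medians of these classes follow in part from the tests that define them. DQ011869 was among these. In all, 42 of the 82 were also called higher at 24 h, where independent lists of these lengths would share 5.99 (Fisher's exact test across probes, two-sided p = 1.18e-26), and 6 were called lower at 24 h. Of the 6 probes lower at 30 min, 6 were also lower at 24 h, where 0.44 would be shared (Fisher's exact test, two-sided p = 1.54e-07). Probes can be copies of one transcript and are not independent, so these p-values are too small. With each time point fitted alone, so that no estimate of the spread was shared, 48 of 84 higher probes were shared where independent lists would share 9.10, and 7 of 8 lower probes where they would share 0.89.

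**Figure D3:**
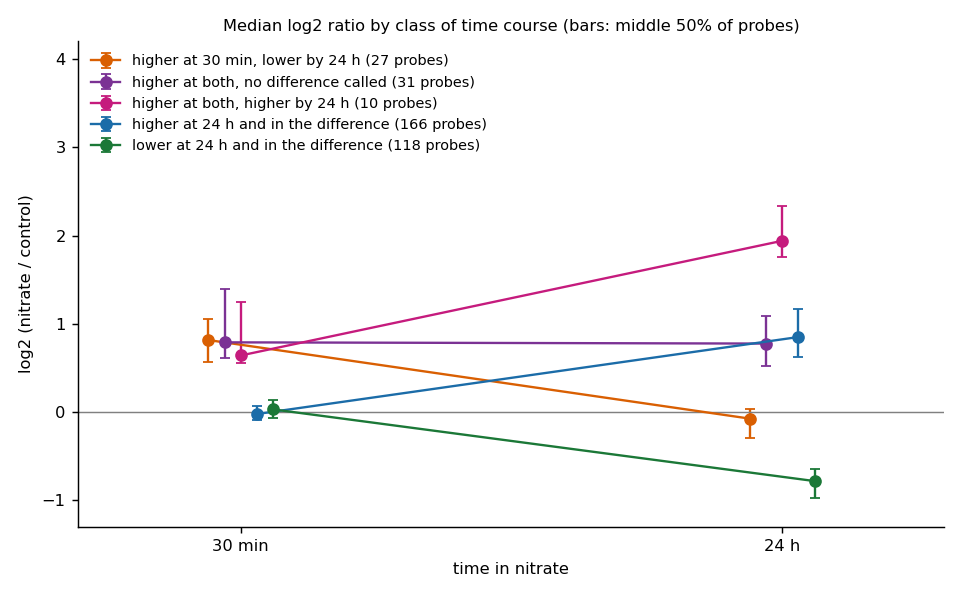
Median log2 ratio of nitrate over control (vertical axis) at 30 min and 24 h for 5 classes of probes set by the tests at each time and of the difference, with bars for the middle 50% of the probes of a class. The class of 27 probes goes from 0.82 to -0.074, the class of 10 from 0.64 to 1.94 and the class of 31 from 0.79 to 0.78. The class of 31 was selected for passing at both times and not in the difference, so its similar medians follow in part from that selection.

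Across all 7688 probes the fitted log2 ratios at 30 min and 24 h correlated weakly, with a Pearson r of 0.33 and a Spearman rho of 0.12. Over the 88 probes that passed at 30 min the Pearson r was 0.74. Their selection for large 30 min ratios of both signs can by itself raise this r, and no rank correlation was computed for them. All these values are correlations across probes, which are not independent replicates, and no array or control was shared between the time points.

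**Figure D4:**
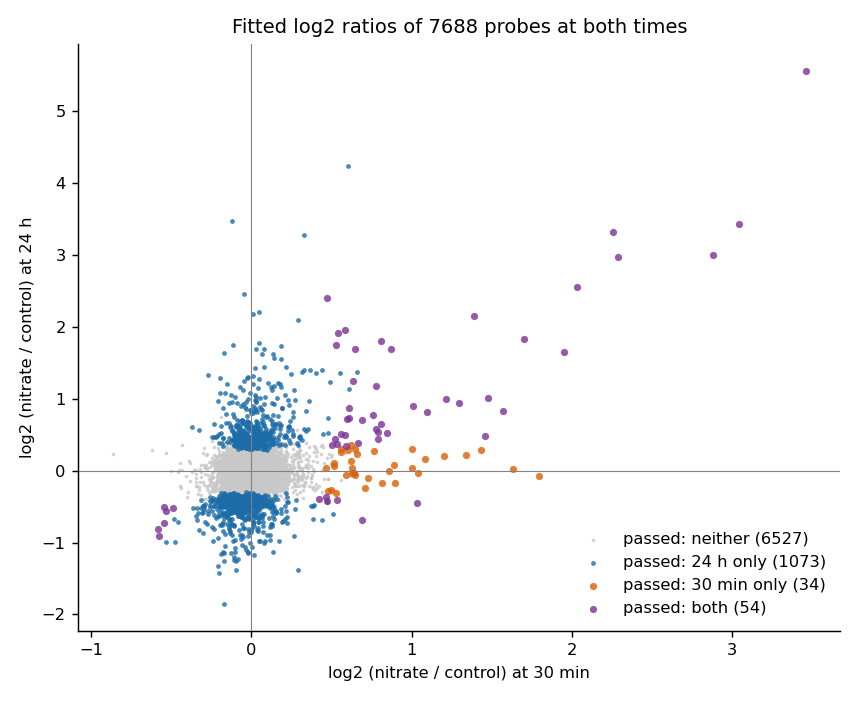
Fitted log2 ratio of nitrate over control at 30 min (horizontal axis) against that at 24 h (vertical axis), with 1 point per probe, coloured by the time points at which the probe passed. Of the 7688 probes, 54 passed at both times, 34 at 30 min but not at 24 h, 1073 at 24 h but not at 30 min and 6527 at neither.

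Of the 3 probes with a name, 0 passed at either time or in the difference. AI665898, paired by the reference table with the gene LOC100191184, which has reticulon among its synonyms, had log2 ratios of 0.03 ± 0.36 (SD, n = 6) at 30 min and -0.03 ± 0.48 (SD, n = 6) at 24 h. The probe that the files call rf2e3 had log2 ratios of -0.02 ± 0.29 (SD, n = 6) and 0.14 ± 0.45 (SD, n = 6). The one they call colim15a had -0.19 ± 0.38 (SD, n = 6) and -0.16 ± 0.65 (SD, n = 6), and its signal was at background in the nitrate channel of 2 of 6 High scans and the control channel of 0 of 6 at 30 min, and in 5 of 6 and 4 of 6 at 24 h, so that its ratio at 24 h carries little information.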

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

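The ratio in nitrate over control differed between 30 min and 24 h, by the model's test of the difference, for 6 of the probes named by rank. The log2 difference, 24 h minus 30 min, was 2.11 ± 0.45 (SE) for BM333948, 3.63 ± 0.27 for BG874013, 3.59 ± 0.25 for DV489508, -1.69 ± 0.18 for BM076073, -1.22 ± 0.18 for BM080220 and -1.87 ± 0.19 for DV492356, with adjusted p-values of 0.00702, 7.84e-08, 3.59e-08, 4.48e-06, 0.000313 and 3.61e-06 (limma). Of these probes BG874013, DV489508, BM076073 and DV492356 were chosen for the size of that difference.

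Of 42 sets of 6 replicates that were searched for a single distant value, 9 held one, where chance gives about 1 in 20. The log2 ratio of BG874013 in 30 min replicate 6 was -0.53, while the other 5 replicates lay between 0.64 and 0.98. Without this replicate BG874013 had a log2 ratio of 0.74 at 30 min and still did not pass (limma, adjusted p = 0.148, with a range of 0.0749 to 1 over all settings). In the Low scan of 30 min replicate 1, the median Cy3 signal was 1318 units against 970.8 to 1040 in the others, and 0.368% of spots were saturated against 0 to 0.114%.

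The other 6 distant values belonged to 24 h replicate 3. Its High scan had a median Cy5 signal of 32040 units against 5483 to 9022 in the other replicates and 30.4% saturated spots against 4.48% to 9.24%. In its Medium scan the median Cy3 signal was 10480 units against 1734 to 2424, the median Cy5 signal 22110 against 1499 to 2954, and 21.9% of spots were saturated against 0.761% to 1.67%. In its Low scan the median Cy3 signal was 1275 units against 477.8 to 716. Leaving this replicate out gave 822 probes at 24 h in place of 1127, while leaving out any other 24 h replicate gave 755 to 947. Without only its High and Medium scans 1243 passed.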

How the results depend on the processing

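The settings for separate dye effects, for subsets of 30 min replicates and without the most saturated scans were chosen after the data had been seen. Apart from replicates left out, 16 of 20 settings gave a count within 1.5 times of 88 at 30 min, 15 of 20 a count within 1.5 times of 1127 at 24 h and 13 of 20 a count within 1.5 times of 326 for the difference. Without a dye effect the counts were 50, 514 and 137, since dye differences then enter the spread. At an adjusted p under 0.01 they were 59, 568 and 173. Array weights gave 129, 1899 and 642, and High scans alone 55, 753 and 182; the cause was not tested. With 30 min replicates 1 to 4 only, which leaves fewer arrays, they were 39, 919 and 197, and with 30 min replicates 5 and 6 only 46, 1720 and 130. Separate dye effects for 24 h, 30 min replicates 1 to 4 and 30 min replicates 5 and 6 gave 128, 2043 and 748. The 30 min ratios were unchanged there, so at 30 min only the spread differed. The deposited values gave 77, 1000 and 285, of which 76, 988 and 279 were among the probes called in the main setting.

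Leaving out 1 replicate at a time gave 58 to 105 probes at 30 min, 755 to 1414 at 24 h and 243 to 465 for the difference. The count of 58 came without 30 min replicate 5 and all 3 upper ends came without 30 min replicate 1. Higher probes made up 89.5% to 100% of the calls at 30 min and 48.5% to 58.2% at 24 h over all settings. The correlation between the times lay between 0.24 and 0.40 over the other settings, within its jackknife error of 0.11 from 0.33. With 1 replicate left out it lay between 0.24 and 0.37. The error was computed from these left-out values, so it is no yardstick for them. The lowest, 0.24, came without 30 min replicate 1, and the next lowest, 0.29, without 24 h replicate 2.

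There were 1049 values of named probes under other settings. Of these, 1007 kept their call or stayed without one, and 42 lost their call. The sign turned in 0 of the values that were called in the main or the other setting. Several settings change only the spread, the threshold or arrays of the other time. They leave a ratio at a given time as it was, so its sign could not turn there. Some values without a call did change sign. The difference of BM073675, for example, went from -0.23 to 0.077 with 30 min replicates 5 and 6 only. Under every setting run for them, 16 of 19 calls were kept. DV489508 was itself among the dimmest 33.3% of the probes and had no value without them. Of the 42 lost calls, 17 belonged to BM073675 and 21 to BG842333, both at 30 min, and 4 to the difference of BM333948. That difference was lost from High scans alone, without a dye effect, with an intensity trend and robust prior and with 30 min replicates 5 and 6 only, at an adjusted p of up to 0.276 and with a log2 difference of at least 1.65 under every setting. With the replicate number as a block, 488 probes passed in the difference, 318 of them among the 326. The labels make the 12 replications separate plants, so the numbers were not taken to pair the samples. Residuals of same-numbered replicates correlated at 0.57, 0.38, 0.23, 0.44, -0.0069 and -0.20. These values cannot decide about pairing, since same-numbered replicates had opposite dye orientations and leftover dye effects can enter the residuals. A factor shared by some same-numbered replicates thus stays open. Tests of gene lists with an estimated correlation or with fry were not run, since 0 probes matched a list. Signal over background limits the dim probes most in the Low scans, where a median of 8.62% of spots were at background. Without the dimmest 33.3% of the probes 67, 956 and 251 passed.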

Other observations

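Some tests were chosen after the results they bear on had been seen. These were the tests of a wrong dye label, of a shift common to all probes and of signs across the sets of 30 min replicates. The share of probes passing at 30 min differed between the re-array and stan collections of clones named in the probe IDs. Of 1747 probes of the re-array collection 1.83% passed at 30 min and 20.0% at 24 h, of 5057 stan probes 0.949% and 12.7%, and of 884 Wholeh probes 0.905% and 15.6%. The odds of passing at 30 min were 1.95 times higher (95% interval 1.20 to 3.12) for re-array than for stan probes. Within 4 equal classes of mean intensity they were 1.99 times higher (1.21 to 3.21), which argues against brightness as the cause. Both intervals treat probes as independent, and they are too narrow where probes are copies of one transcript. Shares at 24 h and those of Wholeh were not compared by a test, and how clones were chosen for the collections was not tested. Of the 9 probes named by rank, 6 came from the re-array collection.

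Many more probes passed at 24 h than at 30 min. The 30 min arrays were noisier, with a median standard error of 0.11 against 0.091 in separate fits, but this was not the whole cause: the variance of the log2 ratios beyond their error was 8.0 times larger at 24 h, and 4.92 to 17.3 times with any 1 replicate left out. A dye effect that differs between the times was argued against as well. With an own dye effect for each time the count was 13.6 times larger at 24 h. That fit does not cover dye effects that differ between the 30 min arrays, which can still widen the spread there. A candidate explanation, as a hypothesis, is that the response of the root transcriptome widened between 30 min and 24 h. The start of treatment also differed, on day 10 for 24 h and on day 11 for 30 min, and its part was not tested.

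Nearly all calls at 30 min were higher in nitrate, 82 of 88 (93.2%). The choice of centring was argued against, since the share was 93.8% under median centring and 98.7% with the deposited values; Aquantile leaves ratios within an array as they are and again gave 93.2%. A floor that hides falls of dim probes was argued against too, since among probes brighter than the median 41 of 42 calls were higher, 97.6% (exact 95% interval 87.4% to 99.9%). What stays open is a shift common to all probes, since every setting centres each scan and so removes it. A shift of 0.13 on the log2 scale would leave 47 higher and 17 lower, against medians of -0.0082 to -0.00046 between the settings, but any one-sided list gives way at some shift, so this value decides nothing.

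The mean Cy5 over Cy3 pattern of the 24 h replicates, in which nitrate cancels, correlated at -0.032, -0.14 and 0.12 with 30 min replicates 1, 2 and 4, against 0.62, 0.75 and 0.72 with replicates 3, 5 and 6. Among the 24 h replicates themselves the correlation was 0.71 to 0.81 within an orientation, where the nitrate effect is shared, and 0.028 to 0.27 between orientations, where it is opposed. A wrong dye label was argued against, since probes called without the replicate had median ratios of 0.54, 0.44 and 0.90 in replicates 1, 2 and 4 (lowest 0.444, under the bound of 0.5 set for this test but far above the negative value a swap would give), and 93.9%, 97.5% and 100% of those called higher were above 0 there. The lowest correlation was -0.142 without background subtraction and -0.155 over the 5312 probes without a saturated spot, which argues against both of these as the cause. A difference in labelling or hybridisation between arrays may remain, but no date or slide is given in the sources used here, and no biological explanation was tested.

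Other assignments of nitrate and control to the channels were tried to see whether chance gives as many calls. At 24 h 1 of 32 assignments, the real one, gave 1127 probes, and the highest other gave 4. For the difference 1 of 100 splits of the 12 replicates, the real one, gave 326, and the highest other gave 6. That argues against chance for both counts but does not exclude it, since only 32 assignments and 100 splits were tried. In assignments other than the real one, the real effect also enters the spread or the dye term, which by itself lowers their counts. At 30 min 2 of 32 assignments gave 88 or more, and the highest other gave 178, so chance could not be excluded by this count. With separate dye effects for 24 h and for both sets of 30 min replicates 1 of the 30 assignments that could be fitted, the real one, gave 128 and the highest other 8, but the one with 178 was not among the 30. Against chance as the source of the whole list, 42 of the 82 higher probes were also called higher at 24 h, on other arrays, and 6 lower, where independent lists would share 5.99 higher probes, and with each time fitted alone 48 of 84 were shared against 9.10. The assignment with 178 put nitrate on Cy3 in replicates 1 to 4 and on Cy5 in replicates 5 and 6, those with higher local background, and thus points to a dye difference between these sets. Each set held both orientations equally, so a dye effect common to a set cancels in the ratios. Within replicates 1 to 4 the dye pattern was not common. Replicate 3 correlated with the mean 24 h pattern at 0.62, and replicates 1, 2 and 4 at -0.032, -0.14 and 0.12. Such a difference within a set does not cancel, and it was not modelled. Signs of calls held across the sets, but this does not test a dye difference between the sets. A dye difference between the sets cancels in the ratios of each set and can change only the spread. Of probes called without replicates 5 and 6, 39 of 39 had the same sign in the replicates left out. Of those called without replicates 1 to 4, 46 of 46 did. These shares were 100% (exact 95% lower bounds of 91.0% and 92.3%), with medians of 1.49 and 0.88 in the called direction. The bounds treat probes as independent and are too high where probes are copies of one transcript.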
